A study of Homo sapiens with 16 samples.

How the data were processed

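The series holds 16 Affymetrix Human Genome U133 Plus 2.0 arrays of 4 human T-cell acute lymphoblastic leukaemia lines, with 2 arrays for each line and treatment. Per the labels' protocols, cells were grown in RPMI with serum, treated for 15 h with DMSO or 1 uM PD-0332991, and total RNA was taken with a Qiagen RNeasy Plus kit. Per the labels' protocols, 5 ng of RNA was amplified with the Nugen Ovation V2 system and the cDNA was labelled with biotin. Per the submitters' processing notes, the values were made with RMA, whose version and probe set definition are not given in the sources used here. The deposited values are intensity values per probe set on a linear scale, from 4.42 to 26097, with array medians of 28.5 to 31.2, so the arrays did not share 1 distribution. The design had assumed log2 values, and log2 was therefore taken first, with no pseudocount and no further scaling. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. No genome build is given in the sources used here, so no coordinates are reported.

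The platform annotation was used to name genes. Of 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were unnamed here, and only the first kind entered the gene tests. The gene identifiers of 41043 probe sets were found in a RefSeq gene table of the assembly GRCh38.p14, used for names alone, and 0 symbols changed. Each of 19775 genes was represented by the probe set with the highest mean over all arrays. A gene was tested where its mean over the 4 arrays of at least 1 line reached the median of all deposited values (29.5, or 4.88 on the log2 scale), which kept 13483 genes and set aside 6292 as dim. Of the genes tested, 8535 had more than 1 probe set. Among the 138 named genes 89 had more than 1. Among the named genes called in the average effect, 1, IKZF1, had a probe set called in the other direction in that effect (7 of its 9 probe sets had the same sign as the one used). Other effects and genes not called were not checked in this way.

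Linear models with 8 group means were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 8 residual and 3.32 prior degrees of freedom), with statmod 1.5.0. The contrasts were PD-0332991 minus DMSO in each line, their average, the differences between lines with an F test on 3 degrees of freedom, and the differences between lines in DMSO. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. All tests were two-sided. Gene lists were tested with camera at its preset correlation, again with an estimated correlation, and with fry, and adjusted over the 20 pathway lists. The lists covered the cyclin D, CDK4 and CDK6, and RB network, replication, nucleotide synthesis, DNA repair, mitosis, histones, MYC and ribosome biogenesis, NOTCH1, p53, the BCL2 family, T-cell genes, FOXO and quiescence, sterols, lysosome and autophagy, glycolysis, the respiratory chain, interferon, antigen presentation, stress responses and immediate early genes. A list of T-ALL factors and 6 lists of markers of other cell types were counted but not set against other genes. The 4 quality measures were compared between treatments with an exact permutation test within lines over 1296 assignments. Correlations between the effects of lines were computed across genes for 6 pairs. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

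The groups, the gene lists, the tests, the other settings to be tried and the rule for named genes were fixed before the data were examined. That rule took the 10 largest rises and falls of the average effect among called genes with the same sign in all 4 lines, and the 5 largest rises and falls in each line among called genes whose 2 PD-0332991 arrays lay outside the range of the DMSO arrays. It also took the 10 genes with the smallest interaction p, the 3 members of each list with the smallest p, a fixed set of cell cycle and survival genes, and T-ALL factors that differed in DMSO. Uncharacterised loci were passed over; there was 1. Other genes are said to be named after their values were seen.

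The fits were tested on simulated data for 13483 genes with known changes. In the average effect 53.7% of genes changed by 0.25 on the log2 scale were called, 98.5% at 0.5 and 100% at 1. For the effect in CEM the shares were 8.96%, 70.1% and 93.9%, and for the effect in Jurkat 5.97%, 52.2% and 92.4%. For the difference between lines they were 0%, 14.9% and 81.8%. Of 13083 unchanged genes 4 were called in the average effect, 18 in CEM, 7 in Jurkat and 4 in the difference between lines. The simulated noise was independent between genes and arrays, with no deviation shared by the genes of an array. Far fewer genes changed than were called in the data, so these shares and counts may not hold for the real arrays. Alternatives covered the choice of probe sets, the dim filter, scaling between arrays, the variance model, array weights, a replicate block, stricter thresholds, other designs and leaving out each array or line. Probe sets without exactly 1 symbol were left out of the gene tests and are counted in the closing section. Some genes of the lists, CDKN2C among them, were not analysed here.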

Results

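Gene expression was measured in 4 established human cell lines of T-cell acute lymphoblastic leukaemia, CEM, CUTL1, DND41 and Jurkat, each exposed to DMSO or to 1 uM PD-0332991 for 15 h. PD-0332991 (palbociclib) inhibits CDK4 and CDK6, the kinases that act with D-type cyclins to phosphorylate the retinoblastoma protein. There were 8 groups of 2 arrays, 16 arrays in all. The deposited values were array intensities from 4.42 to 26097, and the median intensity of an array lay between 28.5 and 31.2. The number of arrays limits the precision of every value below. Changes are log2 differences of PD-0332991 minus DMSO, and 13483 genes were tested.

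Replicate arrays of a group correlated across the genes tested, each with 1 probe set, at r of 0.993 to 0.998. The pair farthest apart was DND41 with PD-0332991, with a median absolute difference of 0.142 on the log2 scale. The probe sets for 18S ribosomal RNA stood at 13.19 on the log2 scale (SD 0.271, n = 8) with DMSO and 12.98 (SD 0.372, n = 8) with PD-0332991, with an exact stratified permutation p of 0.177 (two-sided) and an adjusted p of 0.710. In DND41 the 2 PD-0332991 arrays were at 12.45 and 12.75 and the 2 DMSO arrays at 13.21 and 13.26, and in CUTL1 they were at 12.80 and 12.67 against 13.28 and 13.17. In CEM and Jurkat the arrays of the 2 treatments overlapped. The ratio of signal near the start to signal near the end of the transcript gave exact permutation p-values of 0.690 for actin and 0.883 for GAPDH (n = 8 and 8), and the hybridisation spikes gave an exact permutation p of 0.733. The adjusted value was 0.883 for each of these 3 measures.

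The first comparison asked what CDK4 and CDK6 inhibition did to gene expression on average over the 4 lines. CCNE2, which encodes cyclin E2, fell most among the genes with the same sign in all 4 lines, by 4.34 (SE 0.10), or 20.2-fold (n = 8 arrays per treatment). It was followed by GINS2, a subunit of the replicative helicase, at -3.47 (SE 0.04, 11.1-fold), by ZNF367 at -3.24, and by CDC6, which loads that helicase at origins, at -3.20 (SE 0.05, 9.19-fold). The other large falls were in the repressor E2F genes E2F7 (-3.19) and E2F8 (-2.87), in DTL (-3.09), a substrate receptor for degradation at replication forks, in the nuclease gene EXO1 (-3.02), and in the replication factors MCM10 (-2.93) and CDT1 (-2.73). The largest rises were smaller. TP53INP1, a p53-induced gene with a role in autophagy, rose by 2.10 (SE 0.11), or 4.30-fold. SESN3, a stress-responsive inhibitor of mTORC1 signalling, rose by 1.82 (SE 0.12), the histone genes H2AC6 and H2BC21 by 1.77 and 1.44, and DDIT4, another inhibitor of mTORC1 signalling, by 1.28 (SE 0.03). YPEL2 (1.46), ABAT, which encodes a GABA-degrading enzyme (1.42), the non-coding RNA gene PCAT18 (1.40), PBXIP1 (1.20) and the histone demethylase gene KDM5B (1.14) completed this set. The limma adjusted p-values of these 20 genes ran from 2.95e-13 for GINS2 to 8.16e-07 for H2BC21. In all, 6288 genes (46.6%) were called in the average effect at an adjusted p under 0.05, of which 3594 were higher and 2694 lower with PD-0332991. Among those that changed at least 2-fold the balance was the other way, with 18 higher and 250 lower. With each line's mean difference taken as 1 replicate, 2546 genes were called, 1261 higher and 1285 lower.

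**Figure D1:**
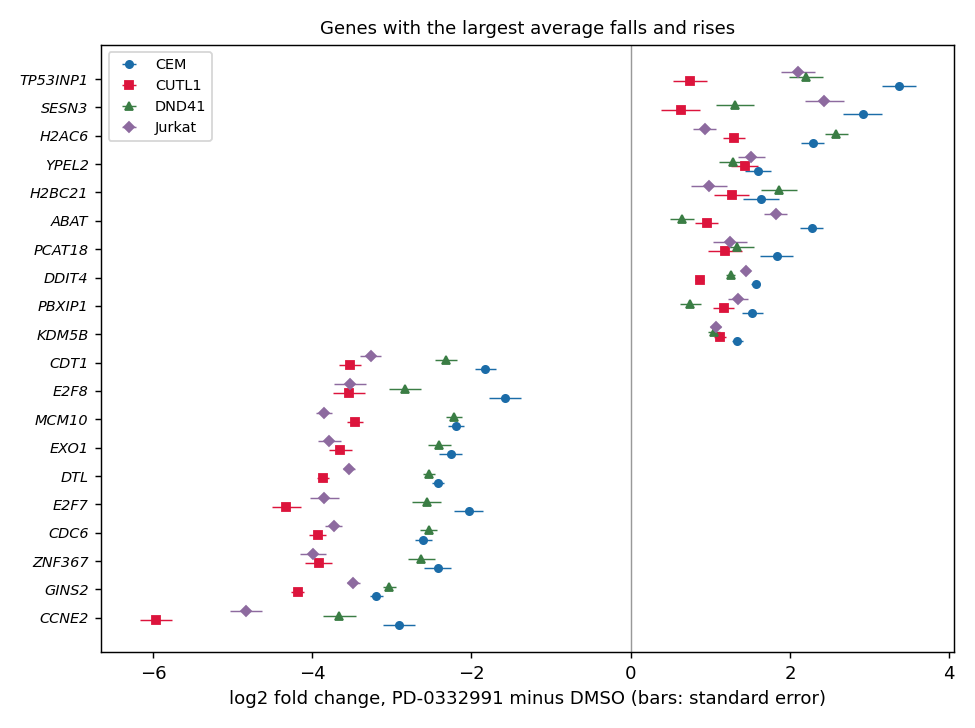
Log2 fold change of PD-0332991 over DMSO for the 10 largest rises and the 10 largest falls of the average effect, with 1 point per cell line, bars for its standard error (n = 2 arrays per group) and genes in the order of the average effect. The lowest point is CCNE2 in CUTL1 at -5.96 and the highest TP53INP1 in CEM at 3.36.

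Genes of DNA synthesis and cell division fell almost as a block. Of 50 measured genes for replication origin and fork proteins 48 fell, with a median of -1.63, for example CDC45 (-2.60) and the flap endonuclease gene FEN1 (-2.08), and the exceptions were ORC2 and ORC5 at -0.03 and -0.01. Of 69 genes of G2 and mitosis 68 fell, with a median of -0.92, among them MYBL2, a transcription factor of late cell cycle genes (-1.84), CDCA5, a cohesion factor (-1.91), and the kinase gene MELK (-1.63). CKS2 (-0.11) was not called. Of 21 DNA repair and replication checkpoint genes 20 fell (median -1.60), including the helicase gene BLM (-1.75) and FANCI of the Fanconi pathway (-1.79), while ATR (0.11) was not called. Of 26 genes of nucleotide synthesis 23 fell (median -0.43), led by RRM2, the regulated subunit of ribonucleotide reductase (-2.48), thymidine kinase TK1 (-2.38) and thymidylate synthase TYMS (-1.43). The members not called were ATIC (-0.10), ADSL (-0.08) and IMPDH1 (-0.11). Adjusted over the list alone, the falls numbered 48, 69, 20 and 25, and 1 DNA repair gene rose. The camera adjusted p-values were 3.68e-44 for replication, 5.32e-42 for mitosis, 1.32e-18 for repair and 1.10e-16 for nucleotide synthesis, and 0.000659, 0.000243, 0.00287 and 0.000243 with an estimated correlation. ORC2, ORC5, CKS2, ATR, ATIC, ADSL and IMPDH1 were named after their values were seen.

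Within the cyclin D, CDK4 and CDK6, and RB network, 17 of 30 measured genes fell, 5 rose and 8 were not called. The phosphatase gene CDC25A (-2.16), E2F2 (-2.19), CCNE1 (-1.90), the pocket protein gene RBL1 (-1.69), E2F1 (-1.15) and the E2F partner gene TFDP1 (-1.14) fell, and so did the drug target CDK4, by 0.65 (SE 0.04). The other target, CDK6, rose by 0.25 (SE 0.04), as did the D-type cyclin genes CCND3 by 0.30 (SE 0.04) and CCND2 by 0.47 (SE 0.07). The last 2 rises, E2F5 (0.26) and TFDP2 (0.22), were named after their values were seen. RB1 stood at -0.10 (adjusted p = 0.238), CCND1 at 0.07 (0.551), CDKN1B at -0.05 (0.570) and CDKN2A at -0.04 (0.696), none of them called, and the CDK inhibitor gene CDKN1A fell by 0.51 (adjusted p = 0.000279). CCND1 lay below the level of 4.88 used to set dim genes aside in 6 of 8 groups, CCND2 in 5 and CDKN2A in 2, where changes are not measured reliably. The CCND2 rise was seen in DND41 and Jurkat and not in CEM and CUTL1, as given below. With all probe sets of a gene averaged, RB1 fell by 0.15 (adjusted p = 0.0237). E2F3 fell by 0.21 (adjusted p = 0.0359), a call that was lost without 1 array in 9 of 16 sets, with adjusted p-values of up to 0.0862. CDKN2C was not analysed here. Adjusted over the list alone, 6 genes were higher and 17 lower. The camera adjusted p of the list was 5.26e-07, and 0.0126 with an estimated correlation.

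**Figure D2:**
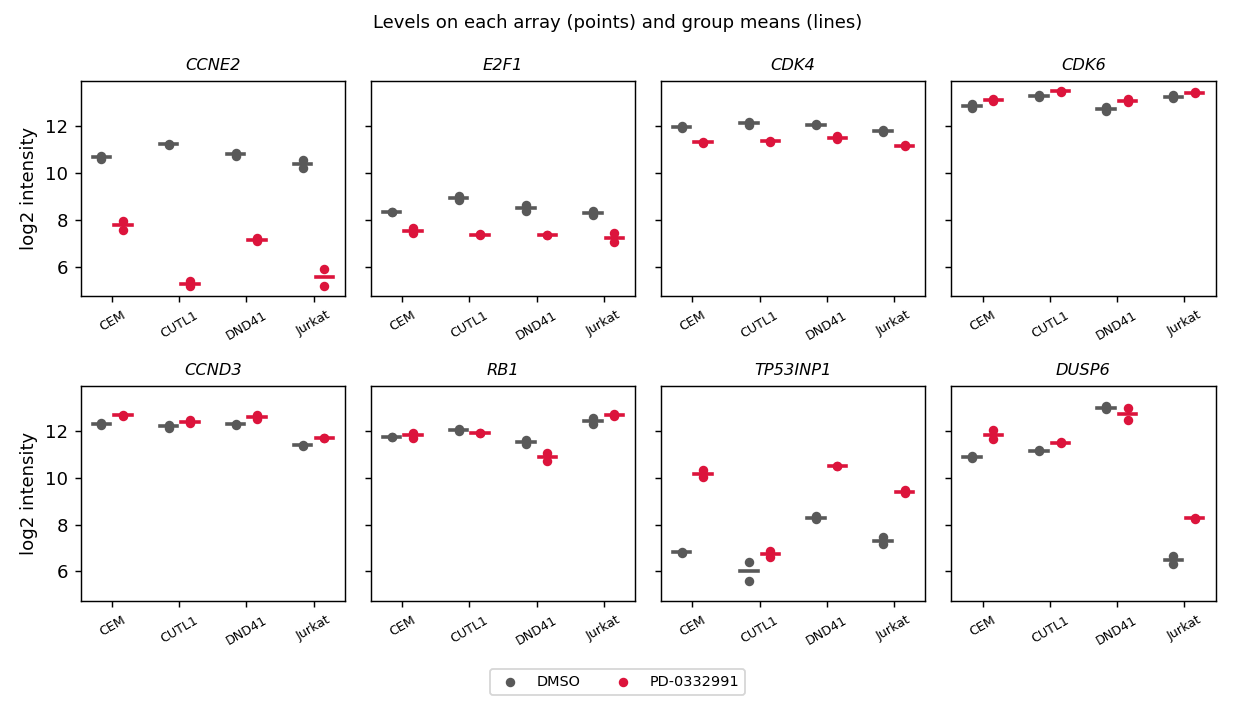
Log2 intensity of CCNE2, E2F1, CDK4, CDK6, CCND3, RB1, TP53INP1 and DUSP6 on each array (points) with group means (lines) for DMSO and PD-0332991 in each line. CCNE2 went from a mean of 11.22 to 5.26 in CUTL1, and CDK6 stayed between 12.75 and 13.50 in all group means.

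T-cell genes rose together by small amounts. Of 46 measured genes of the T cell receptor, coreceptors and thymocyte stages, 38 rose, 3 fell and 5 were not called, with a median of 0.35. Examples were DNTT, which adds nucleotides during receptor rearrangement (0.70), the recombinase gene RAG1 (0.89), the receptor chain gene CD247 (0.47) and the adaptor gene LAT (0.42). The 3 that fell, named after their values were seen, were the chemokine receptor genes CCR7 (-0.30) and CXCR4 (-0.26) and the transcription factor gene RUNX3 (-0.23). The counts adjusted over the list alone were also 38 and 3, with a camera adjusted p of 3.22e-08 and an adjusted p = 0.00602 with an estimated correlation.

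Other lists were called higher in the average effect by camera with its preset correlation and not with an estimated one. In single lines, at the preset correlation, the lysosome list was not called in CUTL1 (camera adjusted p = 0.343) or Jurkat (0.0569). Nor was the antigen presentation list in CUTL1 (0.0923). The FOXO and interferon lists were called higher in every line. The interferon median in DND41 was 0.13, but 0.06 with arrays centred on their medians and 0.20 with quantile normalization. Of 32 genes linked to FOXO, KLF2 and quiescence 24 rose (median 0.38), among them YPEL5 (1.14), the repressor gene HBP1 (0.82) and TXNIP, a thioredoxin-binding protein (0.69). IRS2 (-0.42) and SLFN11 (-0.57) fell and were named after their values were seen. The camera adjusted p was 6.00e-07, and adjusted p = 0.115 with an estimated correlation. Of 39 interferon-stimulated genes 28 rose (median 0.28), such as the exonuclease gene ISG20 (0.97), and 4 fell, the ISG15 ligase gene HERC5 (-1.43), CMPK2 (-0.80), a mitochondrial nucleotide kinase, OAS3 (-0.39) and USP18 (-0.44), the last 2 named after their values were seen. The camera adjusted p was 4.26e-05, and adjusted p = 0.115 with an estimated correlation. Of 21 antigen presentation genes 14 rose (median 0.21), including HLA-E (0.53), HLA-C (0.31) and the immunoproteasome gene PSMB10 (0.33), and TAP2 fell by 0.12, named after its value was seen. The camera adjusted p was 0.00331, and adjusted p = 0.115 with an estimated correlation. Of 41 lysosome and autophagy genes 22 rose (median 0.16), among them the protease gene TPP1 (0.62) and the autophagosome gene MAP1LC3B (0.52), and 4 fell, the galactosidase gene GLA (-0.79) and, named after their values were seen, GUSB (-0.53), MCOLN1 (-0.15) and NPC1 (-0.13). The camera adjusted p was 0.00289, and adjusted p = 0.125 with an estimated correlation. Adjusted over the list alone, higher and lower members numbered 26 and 3 for FOXO, 29 and 4 for interferon, 14 and 1 for antigen presentation and 23 and 4 for lysosome genes.

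**Figure D3:**
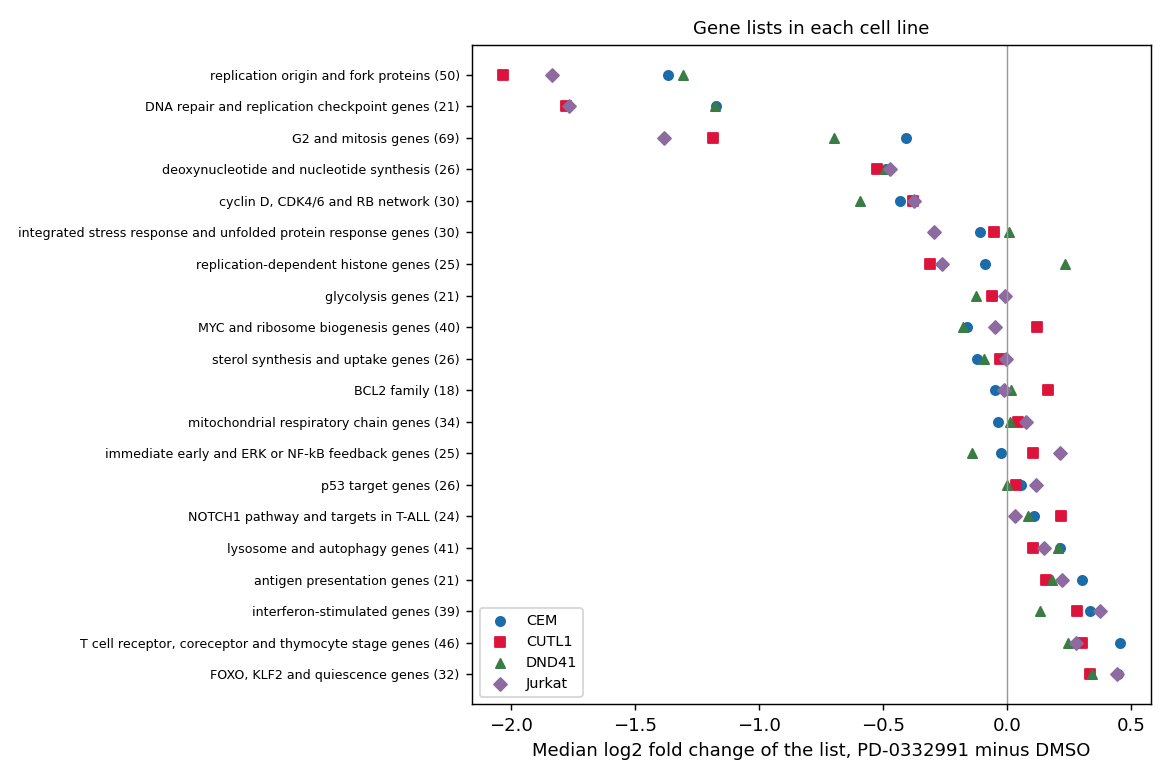
Median log2 fold change of PD-0332991 over DMSO for the members of each of 20 gene lists, with 1 point per cell line, lists in the order of the average effect and the number of genes tested in brackets. Replication genes have a median of -2.03 in CUTL1 and -1.31 in DND41, and the T-cell list lies between 0.25 and 0.45 in all 4 lines.

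MYC and ribosome biogenesis genes differed between lines. Of 40 measured, 16 fell on average, 4 rose and 20 were not called (median -0.08), with falls in LYAR (-0.54) and MRTO4 (-0.53) of ribosome assembly and in ODC1 of polyamine synthesis (-0.33). MYC itself rose by 0.27 (SE 0.05), as did POLR1A (0.31), POLR1C (0.17) and NOB1 (0.15), which were named after their values were seen. The camera adjusted p was 0.00702, and adjusted p = 0.212 with an estimated correlation. It was 0.101 without CEM and 0.0858 without DND41. Higher and lower members numbered 0 and 10 in CEM (median -0.16), 1 and 14 in DND41 (-0.18), 0 and 5 in Jurkat (-0.05) and 10 and 2 in CUTL1 (0.12). The DND41 counts depended on scaling. They were 1 and 22 (-0.25) with arrays centred on their medians, 2 and 10 (-0.09) with quantile normalization and 2 and 11 (-0.09) after cyclic loess. The list was called lower in CEM, DND41 and Jurkat (camera adjusted p = 5.57e-05, 0.00061 and 0.0132) but not with an estimated correlation (adjusted p = 0.0985, 0.152 and 0.257), and was not called in CUTL1 (0.0923). The differences of CUTL1 from CEM, DND41 and Jurkat had an adjusted p = 0.0156, 0.0353 and 0.0405 with an estimated correlation. The list counts adjusted over the list alone were 4 higher and 16 lower.

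The remaining lists were not called by camera in the average effect. Among 25 replication-dependent histone genes 11 fell and 3 rose, H2AC6 (1.77), H2BC21 (1.44) and H2BC12 (0.59), with a median of -0.10, a mean of 0.0024 and a camera adjusted p of 0.145. Each of these 3 genes had 1 probe set with exactly 1 gene symbol. Those of H2AC6 and H2BC21 bore the suffix _s_at, so neither gene was in the alternative fit without _x_at or _s_at probe sets. Among 24 NOTCH1 pathway genes 9 rose, including HES1 (0.51) and IL7R (0.52), and 3 fell, HES4 (-0.68), HEY1 (-0.18) and SHQ1 (-0.20), with an adjusted p of 0.145, and NOTCH1 was at -0.10 (adjusted p = 0.178). Among 26 p53 targets 9 rose and 7 fell, the latter with the repair gene DDB2 (-1.42) and the nuclease gene AEN (-0.58) (adjusted p = 0.894). Of 18 BCL2 family genes 7 rose, such as the anti-apoptotic BCL2L1 (0.40) and MCL1 (0.22) and the pro-apoptotic BIK (0.32), and 3 fell, PMAIP1 (-0.46), BID (-0.18) and BCL2 (-0.26) (adjusted p = 0.730). The BCL2 call was lost with all probe sets of a gene averaged (-0.06, adjusted p = 0.465), and the sign of this list's median of 0.01 turned with arrays centred on their medians. Of 30 genes of the integrated stress and unfolded protein responses 16 fell, including CEBPG (-0.70) and the serine synthesis gene PHGDH (-0.68), and 8 rose, with DDIT4 foremost (adjusted p = 0.0592). Of 26 sterol genes 9 fell, among them EBP (-0.77), ACAT2 (-0.80) and FDPS (-0.46), and SC5D (0.16) and TM7SF2 (0.61) rose (adjusted p = 0.0804). With quantile normalization 5 sterol genes rose and 5 fell, after cyclic loess 4 rose and 6 fell, and with arrays centred on their medians 2 rose and 9 fell. Of 21 glycolysis genes 8 fell, for example ENO2 (-0.77), TPI1 (-0.29) and PFKP (-0.30), the last not called with all probe sets averaged, and SLC2A3 (0.44), ALDOC (0.35), PFKM (0.31), HK1 (0.23) and HK2 (0.20) rose (adjusted p = 0.0957). Of 34 respiratory chain genes 7 rose, such as SDHC (0.26) and UQCRC2 (0.19), and 5 fell, SDHA (-0.24), NDUFS1 (-0.17), NDUFS3 (-0.14), UQCRC1 (-0.14) and CYCS (-0.09) (adjusted p = 0.831). Their balance depended on scaling. Higher and lower members numbered 12 and 3 with quantile normalization, 11 and 4 after cyclic loess and 5 and 6 with arrays centred on their medians. Of 25 immediate early and feedback genes 7 rose, among them TNFAIP3, an inhibitor of NF-kB (0.66), and IER3 (0.34), and 4 fell, IER5 (-0.45), NFKBIA (-0.35), DUSP5 (-0.31) and FOSL2 (-0.22) (adjusted p = 0.758). HEY1, SHQ1, BID, SC5D, TM7SF2, SLC2A3, ALDOC, PFKM, HK1, HK2, NDUFS1, NDUFS3, UQCRC1, CYCS, NFKBIA, DUSP5 and FOSL2 were named after their values were seen.

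Some of these lists were called in single lines. The stress response list was called lower in Jurkat, where 17 of 30 members fell and 4 rose (median -0.29), with a camera adjusted p = 0.000185 and an adjusted p = 0.00833 with an estimated correlation. Its differences between Jurkat and CEM, CUTL1 and DND41 had an adjusted p = 0.00292, 0.0405 and 0.00718 with an estimated correlation. Other calls were not held with an estimated correlation. They were sterol genes lower in CEM (adjusted p = 0.102 with an estimated correlation), NOTCH1 genes higher in CUTL1 (0.0724), immediate early genes higher in Jurkat (0.149), and histone genes lower in CUTL1 (0.27) and Jurkat (0.308) and higher in DND41 (0.274).

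For these 9 lists the counts adjusted over the list alone, higher and lower, were 3 and 11 for histones, 11 and 3 for NOTCH1, 9 and 7 for p53, 7 and 3 for BCL2, 9 and 16 for stress responses, 2 and 9 for sterols, 5 and 8 for glycolysis, 7 and 4 for the respiratory chain and 7 and 4 for immediate early genes. Across the 20 lists, camera called 11, of which 5 were higher, and 6 with an estimated correlation, of which 1, the T-cell list, was higher. The test fry, which asks whether the members move one way on balance and not whether they stand apart from other genes, called 18.

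Markers of other cell types were mostly dim. Among B cell markers CR2 (0.54) and CD79A (0.25) rose of 3 tested, among erythroid and megakaryocyte markers ALAS2 (0.25) of 4, among fibroblast and endothelial markers PECAM1 (0.35) of 5, and among NK and cytotoxic markers PRF1 (0.24), GZMK (0.24) and GZMA (0.30) of 6. None of the 2 myeloid and 4 epithelial markers tested was called, and no marker fell. GZMK and ALAS2 each lay below the dim level in 6 of 8 groups, where changes are not measured reliably. The fibroblast and endothelial list had a median of -0.0012 and a mean of 0.066. The GZMA call was lost without 1 array in 12 of 16 sets, with adjusted p-values of up to 0.0978, and with arrays centred on their medians (adjusted p = 0.0591). Of 19 T-ALL transcription factor and driver genes, 9 rose, including GATA3 (0.37), ETV6 (0.30) and IKZF1 (0.20), and TAL1 fell by 0.32. Adjusted over the list alone the counts were also 9 and 1. The calls of IKZF1 and TAL1 were lost with all probe sets averaged (adjusted p = 0.140 and 0.0871), and 1 of the 9 IKZF1 probe sets was called in the other direction.

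The second comparison took each line by itself (n = 2 arrays per group). In CEM, TP53INP1 rose by 3.36 (SE 0.21), SESN3 by 2.92 (SE 0.24) and SLFN12, a Schlafen family gene, by 1.85, and GINS2 fell by 3.19 (SE 0.09). In CUTL1, CCNE2 fell by 5.96 (SE 0.20), from 11.22 (SD 0.0207) to 5.26 (SD 0.150), near the level of 4.88 used to set dim genes aside, and E2F7 fell by 4.33. CYFIP1, a regulator of actin and translation, rose by 2.57 (SE 0.15) in CUTL1, RAG1 by 1.62, the potassium channel gene KCNJ2 by 1.47 and CREBRF by 1.41. In DND41, H2AC6 rose by 2.58 and PNRC1, a nuclear receptor coactivator gene, by 1.41, and CCNE2 fell by 3.66. In Jurkat, AFAP1, an actin-binding protein gene, rose by 2.74 (SE 0.39) from a DMSO level of 3.66 (SD 1.18), below that level of 4.88, so that the size of this rise is uncertain. In the same line SESN3 rose by 2.43 and DUSP6, an ERK phosphatase gene, by 1.78, and CCNE2 fell by 4.83. The DMSO means of SESN3 in CEM and DND41, of H2BC21 in CEM, DND41 and Jurkat, of PCAT18 in DND41 and of RAG1 in Jurkat also lay below the dim level. So did those of CCND2 in CEM, CUTL1 and DND41. With PD-0332991, H2BC21 in Jurkat and CCND2 in CEM and CUTL1 lay below it. In CUTL1 SESN3 was at 0.63 (adjusted p = 0.078) and was not called. By limma, 3786 genes were called in CEM (2218 higher, 1568 lower), 3673 in CUTL1 (1966 and 1707), 3800 in DND41 (1495 and 2305) and 3645 in Jurkat (2110 and 1535). The split of the effect in DND41 depended on scaling. It was 1919 higher and 1838 lower after cyclic loess, 2156 and 1760 after quantile normalization, and 899 and 2880 with arrays centred on their medians.

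Single arrays moved these counts. For the effect in CEM the count was 2424 without DMSO replicate 1, 2505 without DMSO replicate 2 and 2370 without PD-0332991 replicate 1. For the effect in CUTL1 it was 2447 without PD-0332991 replicate 1. For the effect in DND41 it was 2204 without DMSO replicate 1, 2146 without DMSO replicate 2 and 2312 without PD-0332991 replicate 1, and 1849 genes were called in a fit of DND41 alone. For the effect in Jurkat it was 2210 without PD-0332991 replicate 1 and 2150 without PD-0332991 replicate 2. In the full set, 492 genes were called higher in all 4 lines, where independent lists of these sizes would share 5.61, and 762 were called lower in all 4, where 3.86 would be shared. The lines shared 1 estimate of the spread of each gene, so their lists were not independent and these values are only a rough reference. Of the 7239 genes called in at least 1 line, 240 were called in opposite directions in different lines.

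The third comparison asked where the response differed between lines. RRM2 had the smallest interaction p, with falls of 1.46 in CEM, 1.94 in DND41, 2.99 in CUTL1 and 3.53 in Jurkat (SE 0.08 each, interaction adjusted p = 2.3e-05 from limma). Falls were also smaller in CEM and DND41 than in CUTL1 and Jurkat for TYMS (-0.88, -1.08, -1.80 and -1.98), DTL (-2.42, -2.53, -3.87 and -3.54), MCM10, CDCA5, MELK, the histone chaperone gene ASF1B and PCLAF, a PCNA-binding factor. ETV5, an ETS factor gene induced by ERK signalling, rose in CEM (0.52) and Jurkat (1.46), fell in CUTL1 (-0.39) and was at -0.11 in DND41 (interaction adjusted p = 0.00013). TANC1 fell in CUTL1 (-1.93) and DND41 (-1.10) and was at 0.00 and 0.20 in CEM and Jurkat. DUSP6 rose in CEM (0.93) and Jurkat (1.78) and was at 0.34 in CUTL1 and -0.28 in DND41 (interaction adjusted p = 0.0014). BCL2 fell in CEM (-0.54) and CUTL1 (-0.97) and rose in DND41 (0.54) (interaction adjusted p = 0.00033), while the pro-apoptotic BCL2L11 rose in CUTL1 (0.71) and fell in CEM (-0.54) and Jurkat (-0.39) (interaction adjusted p = 0.0022). CCND2 rose in DND41 (0.85) and Jurkat (1.28) and was at -0.13 and -0.11 in CEM and CUTL1 (interaction adjusted p = 0.0028). Its means in CEM, in CUTL1 and in DND41 with DMSO lay below the dim level, where changes are not measured reliably. MYC rose in CUTL1 (0.59) and DND41 (0.55) and was at 0.13 and -0.17 in CEM and Jurkat (interaction adjusted p = 0.013). RB1 fell in DND41 (-0.62) and was at 0.07, -0.11 and 0.27 in CEM, CUTL1 and Jurkat (interaction adjusted p = 0.032).

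Among lists, the mitosis genes differed most between lines, with medians of -0.41 in CEM, -0.70 in DND41, -1.19 in CUTL1 and -1.38 in Jurkat. The difference between CEM and Jurkat had a camera adjusted p = 2.76e-05 with an estimated correlation, and that between CEM and CUTL1 0.000396. Replication genes had medians of -1.37 in CEM, -1.31 in DND41, -2.03 in CUTL1 and -1.84 in Jurkat, with adjusted p = 0.00566 for CEM against CUTL1 and 0.00450 for CUTL1 against DND41, each with an estimated correlation. Both PD-0332991 arrays lay below both DMSO arrays in 18S signal in DND41 and in CUTL1, the lines with the smallest and the largest median fall of the replication list. Repair genes had medians of -1.17 in CEM, -1.18 in DND41, -1.78 in CUTL1 and -1.77 in Jurkat.

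The difference between lines was called for 1700 genes (12.6%). Between pairs of lines, 266 differed for CEM and Jurkat, 344 for CUTL1 and Jurkat, 693 for CEM and CUTL1, 964 for CUTL1 and DND41, 1255 for CEM and DND41 and 1283 for DND41 and Jurkat. The total was 1129 without CEM DMSO replicate 1, 1041 without CEM DMSO replicate 2, 1113 without CEM PD-0332991 replicate 1, 922 and 1060 without CUTL1 PD-0332991 replicates 1 and 2, 791 and 821 without DND41 DMSO replicates 1 and 2, 1129 without DND41 PD-0332991 replicate 1, and 955 and 941 without Jurkat PD-0332991 replicates 1 and 2. Each of these sets holds a group of 1 array, so a lower total need not mark a deviating array. With a mean-dependent, robust variance prior the total was 2562. It was 2694 with the main axis of the differences between replicates outside DND41 removed, a setting chosen after seeing the data.

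The responses of all 6 pairs of lines were correlated across genes, which are not independent replicates. Pearson's r over 13483 genes was 0.771 for CEM and Jurkat, 0.757 for CUTL1 and Jurkat and 0.692 for CEM and CUTL1. With DND41 it was 0.646 for CUTL1, 0.529 for Jurkat and 0.472 for CEM. Spearman's rho followed at 0.717, 0.589, 0.579, 0.461, 0.328 and 0.30. The lines shared the sign of the change in 75.9% of genes for CEM and Jurkat and in 58.6% for CEM and DND41.

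The last comparison set the lines side by side in DMSO. TAL1, a basic helix-loop-helix factor often activated in this leukaemia, was at 11.22 (SD 0.00763) in Jurkat, 8.89 (SD 0.0584) in CEM and 8.30 (SD 0.102) in DND41, and at 4.29 (SD 0.181) in CUTL1 (n = 2 each, limma adjusted p = 2.1e-11). DND41 had the highest levels of the homeobox gene TLX3 (6.86, others 3.23 to 3.50) and of LMO1 (9.18), and CEM those of NKX2-5 (10.72) and LMO2 (8.01). HHEX and ERG were high in CEM (9.30 and 8.50) and DND41 (9.82 and 9.32) and low in CUTL1 (3.48 and 3.79) and Jurkat (5.16 and 4.54). CDKN2A, which encodes inhibitors of CDK4 and CDK6 and of MDM2, was at 9.84 in CUTL1 and 10.73 in DND41 but at 4.81 and 5.17 in CEM and Jurkat, near or below the dim level. CCND3 and CDK6 were bright in every line, at 11.40 to 12.30 and 12.75 to 13.28. NOTCH1 was at 10.91 in CUTL1 and 9.02 in Jurkat. By limma 18 T-ALL factor and driver genes and 9595 of all 13483 genes (71.2%) differed between lines in DMSO.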

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

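The tests of the lower correlation of DND41, of a shift of all genes and of signal from other histone genes were chosen only after those results were seen. The test of a shift took the place of an earlier comparison with random lists matched on level, of which at most 9 of 10000 had a median as high. That comparison repeated the call against other genes, and so does the test of a shift, which sets the lists against all genes. The histone test was also changed 3 times after its values were seen. Its first bound, a median of the other genes above 0, would have counted the median of 0.0374 for the explanation. The next, a median above 0 by more than its standard error of 0.0659, left it undecided, a later one set all 3 genes against the highest of the others and argued against it, and the test given here does so for H2AC6 apart, with genes below the dim level taken to decide nothing.

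The response to PD-0332991 differed between cell lines, by limma's interaction test, in 1700 genes, 65 of the 138 named genes among them. Named genes were chosen in part by their interaction p and by their changes in single lines. Their share is raised by that choice and does not compare with that of all genes. The sizes given here are the highest minus the lowest line on the log2 scale. Among genes of replication and its control they were CCNE2 (3.05), GINS2 (1.15), CDC6 (1.39), DTL (1.45), MCM10 (1.66), CDT1 (1.70), CDC45 (1.12), FEN1 (1.02), ASF1B (1.39) and PCLAF (1.30). Among E2F, cyclin and RB network genes they were E2F7 (2.29), E2F8 (1.96), E2F2 (1.66), CCNE1 (1.20), CCND2 (1.41), CDC25A (1.02), TFDP1 (0.57) and RB1 (0.90). For nucleotide synthesis they were RRM2 (2.07), TK1 (1.03) and TYMS (1.10), for repair EXO1 (1.53), BLM (1.04) and FANCI (1.15), and for mitosis CDCA5 (1.43), MELK (1.11) and MYBL2 (1.21). Among the genes that rose on average they were TP53INP1 (2.62), SESN3 (2.29), H2AC6 (1.65), H2BC12 (0.64), ABAT (1.63), DDIT4 (0.70) and TXNIP (0.68). Among genes singled out in 1 line or by the interaction they were AFAP1 (3.07, from levels below the dim level in 7 of 8 groups and so of uncertain size), CYFIP1 (2.43), TANC1 (2.14), DUSP6 (2.06), ETV5 (1.85), SLFN12 (1.65), KCNJ2 (1.40), RAG1 (1.33), PNRC1 (0.79) and ZNF367 (1.56). Survival and p53 genes gave BCL2 (1.52), BCL2L11 (1.26), BIK (1.12), PMAIP1 (1.11) and AEN (0.57). T-ALL factors and T-cell genes gave TAL1 (1.32), PHF6 (0.94), NOTCH1 (0.82), HHEX (0.77), HES4 (1.00), MYC (0.76) and LAT (0.42). The rest were CMPK2 (1.67), GLA (1.32), HERC5 (0.91), ALAS2 (0.81), PHGDH (0.77), CEBPG (0.71), ENO2 (0.58), EBP (0.52) and ODC1 (0.47). Of these 65 genes 12 had at least 1 group mean below the dim level, where log differences are uncertain: AFAP1, ALAS2, CCND2, E2F7, EXO1, HHEX, KCNJ2, RAG1, SESN3, SLFN12, TAL1 and TANC1. These differences were not explained further, and the cell line itself stays open as an untested source.

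For 9 of the 20 gene lists at least 1 pair of lines differed by camera with the preset and with an estimated correlation, in 24 of 120 combinations of list and pair (51 with the preset correlation alone). The highest minus the lowest line median was 0.97 for mitosis, 0.72 for replication, 0.61 for DNA repair, 0.54 for histones, 0.30 for MYC and ribosome biogenesis, 0.30 for stress responses, 0.22 for the RB network, 0.19 for NOTCH1 and 0.051 for nucleotide synthesis. Outside the gene tests, 13578 probe sets had no symbol or several, 4979 of them above the dim level in at least 1 line. Of these 1311 were called in the average effect, 774 higher and 537 lower, and 40 changed at least 2-fold.

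The count of 6288 genes in the average effect was set against other splits of the arrays within lines. Of 100 splits, drawn from 648 and including the real one, 1 gave as many, the real one itself. This argues against a chance split of the arrays as the source of this count, though 100 draws can give no share below 1 in 100. The arrays of a group may share a culture, so the splits cannot tell the drug from a difference between cultures. The highest other split called 3258 genes and parted the arrays as the treatments do in all 4 lines but with 1 line turned round.

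The response of DND41 correlated less with the other lines (mean r 0.549) than the lowest of the other 3 pairs (0.692). An axis shared by arrays was taken from replicate differences within the groups of the other lines, and so from no DND41 array and no difference between treatments. It carried 32.9% of those differences and may account for part of the pattern. The axis correlated with the DND41-specific response at a size of r of 0.576 over 5532 genes with no effect elsewhere at an unadjusted p of 0.05. Over all genes it did so at 0.542, against 0.398, 0.0349 and 0.339 for CEM, CUTL1 and Jurkat. PD-0332991 groups were among those used, so the axis may hold differences in response between replicates, and whether it is technical is not known. This axis was not the whole, because with it removed the mean r reached 0.638 against 0.712 and stayed below in 16 of 16 sets without 1 array (gaps of 0.0503 to 0.158). Cyclic loess (0.559) and leaving out DND41 PD-0332991 replicate 1 (0.584, and 0.471 without replicate 2) also left the mean r well under 0.692, which argues against scaling that depends on intensity or that array as the whole cause. A response particular to DND41 stays open and was not tested separately.

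The T-cell, FOXO, lysosome, interferon and antigen presentation lists were called higher with PD-0332991 in the average effect. The median of all genes was at most 0.0377 with the values as deposited and under quantile, centring and cyclic loess scaling. The list medians lay above it by 0.121 to 0.353 (at least 2.49 bootstrap standard errors, taken over genes as if independent). The lists were called against the other genes, so this gap repeats that call and does not decide on a shift from scaling. The axis of replicate differences, as a cause, would carry the calls away when removed. With it projected out, 5 of the 5 lists were still called at the preset correlation, which argues against that axis as the whole cause. With an estimated correlation the T-cell list alone held, so that a shared rise of the other 4 remains a hypothesis. A link of these lists to CDK4 and CDK6 inhibition itself could be either direct or through arrest of the cell cycle, and no test here separates these.

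In the average effect H2AC6, H2BC12 and H2BC21 rose, while 11 of the other tested members of the histone list fell and 11 were not called. H2AC25, outside the list and named after its value was seen, also rose (0.68). The lines differed, with higher and lower members of the list numbering 3 and 3 in CEM, 3 and 7 in CUTL1, 8 and 4 in DND41 and 3 and 9 in Jurkat. In DND41 another tested H2B gene rose by 1.09 and H2BC12 by 0.95. Signal from the other histone genes tested here is argued against as the whole cause of the H2AC6 rise in the average effect, since H2AC6 exceeded the highest of 10 other H2A genes (H2AC25) by 1.09 (SE 0.09), though not in Jurkat, and 2 of the 10 had a group mean below the dim level. It stays open for H2BC12 and H2BC21, whose gaps to the highest of 7 other H2B genes (H2BC4, 0.22) were 0.371 and 1.22, because H2BC4 and H2BC21 each lay below the dim level in 4 of 8 groups, and so do signal among the 3 genes, signal from histone genes not tested here, and 1 faulty probe set per gene, for which there were 0 other probe sets. A general rise of histone genes used outside S phase is argued against, with 1 of 5 higher (MACROH2A2, 0.26, adjusted p = 0.0422) and 2 lower (H1-10, -0.27, and MACROH2A1, -0.12), these 3 named after their values were seen. Polyadenylated transcripts of the 3 genes in cells that leave the cycle are a candidate source that was not tested.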

How the results depend on the processing

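Cyclic loess, removal of the replicate axis, the crossed pairing in DND41 and the lists without DND41 PD-0332991 replicate 1 were chosen after seeing the data. Among named genes and gene lists no called direction reversed in the settings run for them, but 1 of the 9 IKZF1 probe sets, tested singly, was called in the other direction. Of 219 values for counts and correlations under alternatives, 147 stayed within the limits set and 72 moved. Of 180 values for gene lists 158 kept their side of the threshold, 15 gained a call and 7 lost it, and of 533 for named genes 525 kept theirs, 1 gained a call (RB1) and 7 lost it. The losses were of PFKP, IKZF1, BCL2, TAL1 and ERG with probe sets averaged, GZMA with arrays centred and E2F3 with the block. Without 1 array, 4 of 115 named genes called in the average effect lost the call in at least 1 set (E2F3, GZMA, AFAP1 and WT1), 0 of 40 in a line did, and 0 turned sign. WT1 was lost only without CEM PD-0332991 replicate 1 (adjusted p = 0.0508) and AFAP1 in 11 of 16 sets. An array left alone in its group was assumed to vary like the others, and the mean of that group was less precise. Fewer calls in such a set need not mark a deviating array. Signal over background limits what could be seen, with 6292 genes set aside as dim.

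Testing all probe sets singly, which tests more units, called 11323 for the average effect, 5851 for the effect in CEM, 5806 for the effect in CUTL1, 6656 for the effect in DND41 and 5606 for the effect in Jurkat. An adjusted p under 0.01 left 2170, 2287, 1994 and 2137 in these lines and 528 for the difference between lines, and 4845 on average. A change of at least 2-fold left 268 on average, 280, 473, 322 and 383 in the lines and 486 for the difference. The difference between lines also moved to 2562 with a mean-dependent, robust prior and to 2694 with the replicate axis removed, and the cause was not tested. A fit of DND41 alone, with fewer arrays to estimate the spread, called 1849, and the 4 lines taken as replicates called 2546, of which 2542 were among the 6288 of the average effect and 0 had the opposite sign. Lists called numbered 6 with an estimated correlation and 18 with fry. Without CEM, CUTL1, DND41 or Jurkat the average effect called 5446, 5502, 6200 and 5417 genes. Cyclic loess kept each total of genes called in a comparison within 1.5 times.

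Correlations over genes called in at least 1 of the lines were 0.776 for CEM and CUTL1, 0.599 for CEM and DND41, 0.829 for CEM and Jurkat, 0.718 for CUTL1 and DND41, 0.819 for CUTL1 and Jurkat and 0.623 for DND41 and Jurkat. Over all genes with the replicate axis removed, the correlations with DND41 were 0.597 for CEM, 0.685 for CUTL1 and 0.631 for Jurkat, against 0.472, 0.646 and 0.529 with it. Over all genes, leaving out 1 array gave 0.634 to 0.705, 0.362 to 0.554, 0.722 to 0.763, 0.575 to 0.676, 0.694 to 0.766 and 0.413 to 0.612 for CEM with CUTL1, DND41 and Jurkat, CUTL1 with DND41 and Jurkat, and DND41 with Jurkat. It gave 5770 to 6455 genes for the average effect, 2370 to 2919 for the effect in CEM, 2447 to 3229 for the effect in CUTL1, 2146 to 4012 for the effect in DND41, 2150 to 3280 for the effect in Jurkat and 791 to 2512 for the difference between lines.

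Arrays of the same replicate number deviated together at r of 0.076 in CEM, 0.195 in CUTL1, -0.108 in DND41 and 0.105 in Jurkat, across genes, so the numbers were not taken to pair the arrays. With the replicate number within lines as a block, the counts were 6088 for the average effect, 3363 for the effect in CEM, 3303 for the effect in CUTL1, 3462 for the effect in DND41, 3252 for the effect in Jurkat, and 1079 for the difference between lines. With DND41 paired crosswise, 3681 genes were called in DND41.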

Other observations

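The grouping of genes by shared symbol and the further genes named here were chosen after the values were seen. All tests in this part are exploratory, except that of the immediate early list, which was planned. Of 453 families of at least 5 genes that share the letters of their symbol, 19 were called by camera, 5 of them higher. Nucleoporin genes, which build the nuclear pore, fell together, 19 of 23 (the group also takes in NUP50-DT and NUP62CL by name), with a median of -0.37 and, for example, NUP155 at -1.06 (SE 0.04), NUP85 at -0.99 and NUP107 at -0.60. Their adjusted p was 3.16e-08, and 0.0454 with an estimated correlation, and no other family was called with an estimated correlation. All 7 HAUS genes, subunits of the augmin complex of the spindle, fell (median -0.65, HAUS8 at -1.58), and so did 7 of 10 EXOSC genes of the RNA exosome (EXOSC2, -0.52) and 8 of 13 LSM genes of RNA processing complexes (LSM2, -0.41). The adjusted p-values of these 3 were 0.416, 0.584 and 0.416 with an estimated correlation. All 5 butyrophilin (BTN) genes rose (median 0.57, BTN3A2 at 0.79 and BTN3A1 at 0.57), as did 4 of 5 STAT genes (median 0.49, STAT3 at 0.49), with adjusted p = 0.416 with an estimated correlation for each. The sign of the median of each of these families was the same under quantile normalization, cyclic loess and centring on array medians.

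Of genes that respond to ERK signalling, 4 were looked at by line. EGR1, an immediate early transcription factor gene, rose in Jurkat (1.48) and CUTL1 (0.64), fell in DND41 (-1.0) and was at 0.06 in CEM, with a limma interaction adjusted p of 0.00062. CD69, an early activation antigen, rose in Jurkat (1.61) and CEM (1.05) and was at -0.64 in DND41 and 0.57 in CUTL1, not called there (interaction adjusted p = 0.0063). SPRED1, an inhibitor of the pathway, fell in DND41 (-1.09) and was at 0.39 in Jurkat, 0.07 in CEM and 0.10 in CUTL1, not called there (interaction adjusted p = 0.032). SPRY1, another inhibitor, was at 0.86, 0.81, 0.24 and 0.46 in CEM, CUTL1, DND41 and Jurkat, with no difference between lines called (interaction adjusted p = 0.205). The list of immediate early and feedback genes, fixed before the data were examined, differed between DND41 (median -0.14) and Jurkat (0.21) with a camera adjusted p = 0.00225, but an adjusted p = 0.0679 with an estimated correlation, so that no shared difference was called. In DMSO, DUSP6 was at 13.01 in DND41 and 6.49 in Jurkat, the lines at the opposite ends of these changes for EGR1 and DUSP6.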
